A study of Mus musculus with 16 samples.

How the data were processed

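Liver RNA of wild-type C57BL/6 mice was measured by RNA sequencing in 16 libraries, 8 from mice given emodin and 8 from mice given the carrier alone. Per the labels' protocols, mice were acclimated for 7 days, emodin at 400 mg/kg was given into the stomach over 3 weeks, suspended in sodium carboxymethyl cellulose (0.5%), and livers were taken right after euthanasia that followed the last dose. Libraries were made from 1 µg of total RNA, per the labels' protocols. The labels number 8 titles per group and the protocol speaks of mice, without saying that each library came from its own animal. The p-values therefore measure differences between libraries, each taken as 1 mouse.

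The deposited table holds estimated counts per gene, whole numbers scaled neither by library size nor by gene length, although its name speaks of FPKM. The unit was read from the values: 0 values were not whole numbers, and the totals of the 16 columns lay between 28.3 M and 48.2 M (M, mega). In all 16 livers the value 2 was commoner than the value 1 (632 to 751 entries at 2 against 161 to 207 at 1), so a value of 1 need not stand for 1 read. Per the submitters' processing notes, cutadapt 1.9.1, HISAT2, SAMtools 0.1.19, HTSeq 0.6.1 and Cufflinks 2.2.1 were used with the mm10 genome. These notes give no roles, so which program made the deposited estimated counts, from which annotation and after which filter, is not known. How reads shared between genes were handled is not stated either, so values of close paralogs (Saa1 and Saa2, the Orm, Cyp2a, Gstm, Mup, Hba and Ugt1a genes) are uncertain one by one. All 16 numeric columns were used (0 were left aside).

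The table has 27446 entries, 21833 with an Ensembl gene ID and 5613 named as loci without one. Of the Ensembl IDs, 21779 were found in GENCODE M21, the annotation of mm10 used for coordinates, and 21126 had the same symbol there. Loci without an Ensembl ID took between 4.03% and 4.73% of the counts of a liver. They were kept in the tests, and counts of called entries are given with and without them.

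The depth was 34.1, 33.5, 32.0, 29.4, 28.7, 31.4, 30.6 and 38.6 M estimated counts in vehicle livers 1 to 8, and 34.9, 44.3, 46.0, 38.6, 28.3, 48.2, 35.0 and 33.8 M in emodin livers 1 to 8. The estimated counts carry no molecular identifiers, so counting error is only part of the error, and the spread between livers was used for every test.

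Entries were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with its defaults, TMM scaling factors (0.929 to 1.16), robust dispersions and the robust quasi-likelihood F test, with group as the single term. P-values were adjusted by the Benjamini-Hochberg method over the 14308 entries tested, and an adjusted p under 0.05 was called. The values are whole, so the rounding that the count model needs changed nothing. Levels are in CPM after TMM scaling, given as mean ± SD of 8 livers, and log2 fold changes (emodin over vehicle) are given with a standard error computed as the absolute log2 fold change divided by the square root of F. A gene was called 2-fold changed at an absolute log2 fold change of at least 1.

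The design fixed 42 gene lists before the data were examined, along with the samples, the tests, the named genes and most of the alternatives; 41 lists had at least 3 tested members. They cover the P450 family, the NLRP3 inflammasome, NF-κB, targets of AhR, CAR and PXR, NRF2, PPARα, p53 and glucocorticoids, phase II enzymes, transporters, bile acids, cholesterol, fatty acids, sugars, amino acids, mitochondria, ribosomal proteins, acute phase, interferon, ER stress, cell cycle, heat shock and immediate early genes, the clock, sex-biased genes, fibrosis, lobule zones, and markers of other cells and tissues. Each list was compared with all other tested entries by camera from limma 3.58.1 with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 41 lists, and again with a correlation estimated from the data. The rotation test fry was run beside it; its directional p asks whether the genes of a list move, on balance, to 1 side, its mixed p whether they change in either direction, and neither compares the list with other genes. Of the 41 lists, 19 were called by camera (8 up and 11 down), 0 with an estimated correlation, 1 by fry and 25 by fry's mixed test. A score per liver, the mean log2 CPM of the tested members with a prior count of 2, was compared by an exact two-sided permutation test over all 12870 assignments, and 2 lists passed after adjustment. Members were also counted after Benjamini-Hochberg adjustment over the list alone. Members absent from the table were Mx1, Ctgf, Trac, Trbc2, Ighm, Ighd, Iglc2, Igkc, Ahsp and Amy2b.

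Genes were named by a rule set beforehand: the 10 called genes with the largest rise and the 10 with the largest fall among those with at least 2 CPM in the higher group, up to 4 called members per list (or 2 uncalled ones with the smallest p), 13 genes of the NF-κB and NLRP3 system, 10 P450 genes and 4 control genes. Among the 10 largest falls 7 were loci without an Ensembl ID, so the rule for falls was applied to annotated genes and 2 such loci are named. Cyp4f17, Cyp2r1, Cyp4f14, Cebpd, Tsc22d3 and C8a were added because they completed counts of 5 or fewer in a list, and they and the genes under "Other observations" that fall outside the rule were chosen after their values were seen. The unit expected beforehand was FPKM with limma; the plan named edgeR for the case that the table held counts.

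The alternatives were DESeq2 1.42.0, no filter on low values, a filter at a mean of 5 CPM, median-of-ratios factors, no scaling beyond the totals, scaling without the 50 most abundant genes, no trend and no robust fit, limma on log2 CPM with pseudocounts of 1, 0.1 and 0.01, quantile normalization, array weights, an exact rank-sum test, the replicate number as a block, a test against a fold of 1.2, a ratio of group means, annotated genes alone, halved counts, each liver left out in turn, and leaving out 2 livers together. DESeq2, the 5 CPM filter, no scaling beyond the totals, the limma fits on log2 CPM, annotated genes alone, halved counts and leaving out 2 livers were chosen after seeing the data. Random splits of the livers (100, the real one included) were refitted in the same way.

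The method was tested on simulated data: counts were drawn for 14157 genes of the 16 livers, some of them changed by known folds. Of the genes changed 1.5-fold, 26 of 67 (38.8%) were called, of those changed 2-fold 40 of 67 (59.7%), and of those changed 4-fold 61 of 63 (96.8%). The calls held 6 unchanged genes (4.5%). Of 41 unchanged lists 1 was called, and a list raised 1.5-fold was called. Genes were drawn independently of each other, with the same dispersion in both groups. The simulation therefore cannot give the error rates for lists whose members vary together, or for a group with a wider spread. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No reads were available, so alignment, isoforms and strand were left out, and the in vitro part named in the series title has no samples in the series.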

Results

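Total RNA of 16 mouse livers was sequenced, 8 from mice dosed for 3 weeks with emodin, an anthraquinone of rhubarb and related medicinal plants, and 8 from mice that received the carrier alone (vehicle). The libraries held 28.3 M to 48.2 M estimated counts (M, mega), with 32.3 ± 3.15 M in the vehicle group and 38.6 ± 6.92 M in the emodin group (SD, n = 8 each, exact two-sided permutation p = 0.0359). Of the 27446 entries of the table, 14308 had enough counts to be tested, 12859 of them annotated genes. The comparison of emodin with vehicle addresses how the liver responds to a dose linked to liver toxicity, and the series title points to P450 enzymes and to NF-κB and NLRP3.

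Livers of emodin-dosed mice carried far more mRNA for acute phase proteins, which the liver secretes in inflammation, and for metallothioneins, which bind zinc and copper, and less mRNA for some enzymes that make fatty acids and sterols (6 of 19 and 3 of 24 genes passed). Lcn2, which encodes the iron-siderophore binding protein lipocalin 2, rose 61.0-fold, from 5.20 ± 1.74 to 318 ± 379 CPM (mean ± SD, n = 8 in each group throughout; log2 fold change 5.93, or 3.03 with array weights), and Mt2 rose 13.9-fold, from 28.8 ± 17.8 to 401 ± 331 CPM. The size of the rise of Lcn2 differed between livers, with 279 to 1058 CPM in emodin 2, 4, 5 and 8. The other emodin livers had 7.66 to 61.1 CPM, against up to 8.41 CPM in the vehicle livers. Interferon-induced genes such as Isg15 rose from 4.80 ± 1.2 to 83.2 ± 99.2 CPM, with the same 4 of the 8 emodin livers above every vehicle liver. Bcl6, a transcriptional repressor, fell 4.77-fold from 66.1 ± 19.4 to 13.9 ± 5.45 CPM, and Sc5d, an enzyme of the last steps of cholesterol synthesis, fell 2.05-fold from 603 ± 86.9 to 294 ± 43.9 CPM, each in 8 of 8 emodin livers below every vehicle liver. Of the systems named in the title, 7 of 64 P450 genes (5 lower and 2 higher), 7 of 29 NF-κB components and targets (all higher) and 0 of 17 inflammasome genes passed the test. Of all tested entries 13.2% passed, a larger share than in the P450 family and a smaller one than in the NF-κB list.

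The quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment called 1884 of the 14308 entries (13.2%), 1102 higher and 782 lower with emodin, of which 1028 and 666 were annotated genes. At least 2-fold changes were found for 259 entries upward and 117 downward, and 4249 entries had an unadjusted p under 0.05. The excess of 2-fold rises was not kept in every alternative: array weights gave 94 upward and 102 downward, and the replicate block 108 and 112. It was kept but smaller in the rank-sum test (135 and 104) and with quantile normalization (76 and 50). The same held for limma with pseudocounts of 0.1 (148 and 130) and 0.01 (150 and 138). The balance between higher and lower calls depended on scaling: leaving the 50 most abundant genes out of the scaling factors gave 805 higher and 970 lower, and quantile normalization gave 776 and 1003. Single livers moved the counts as well: without emodin 4 the higher calls numbered 709 and the 2-fold higher ones 167, and without emodin 2 the lower calls numbered 521. Albumin mRNA (Alb), the most abundant hepatocyte transcript, took 8.34 ± 0.821% of the counts of vehicle livers and 5.95 ± 1.07% of those of emodin livers (exact two-sided permutation p = 0.000311).

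The 10 largest rises were those of Lcn2, Saa2, Atf3, Saa1, Prtn3, Orm2, Isg15, Gdf15, Rsad2 and Ifit1, with log2 fold changes from 5.93 down to 4.01 (edgeR adjusted p from 0.00131 to 0.0185). Prtn3, which encodes a serine protease best known from neutrophil granules, rose from 0.233 ± 0.149 to 8.59 ± 9.21 CPM and was higher in all 8 emodin livers than in any vehicle liver. Its log2 fold change of 5.19 went down to 2.36 over its alternatives. The 10 largest falls among annotated genes were those of Bcl6, Chrna4, Nrep, Socs2, Tesmin, 1810046K07Rik, Abcd2, Serpinb1a, Cyp2a22 and Nes, with log2 fold changes from -2.25 to -1.46 (edgeR adjusted p from 0.000167 to 0.0147). Abcd2, a peroxisomal transporter of very long chain fatty acids, fell 3.08-fold from 40.2 ± 10.8 to 13.1 ± 5.76 CPM, and Nrep fell 3.22-fold from 12.9 ± 6.12 to 4.02 ± 1.42 CPM, each below every vehicle liver in 8 of 8. Among loci without an Ensembl ID, NewGene_6584 fell by 2.92 and NewGene_5545 fell by 2.34 on the log2 scale. Of the 10 rising genes 2 kept their call in every alternative (Saa1 and Prtn3), against 7 of the 10 falling ones (all but Chrna4, Socs2 and Serpinb1a), and no left-out liver ended any of these 20 calls. Chrna4 and Serpinb1a each lost their call in 1 alternative and Socs2 in 2 (edgeR or rank-sum adjusted p over the alternatives up to 0.063, 0.0543 and 0.0613, from 9.54e-05, 0.000428 and 0.00012). On mm10, the protein-coding genes Lcn2, Bcl6 and Sc5d lie on chromosome 2 from 32384633 to 32388252, on chromosome 16 from 23965052 to 23988852, and on chromosome 9 from 42251595 to 42264256.

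**Figure D1:**
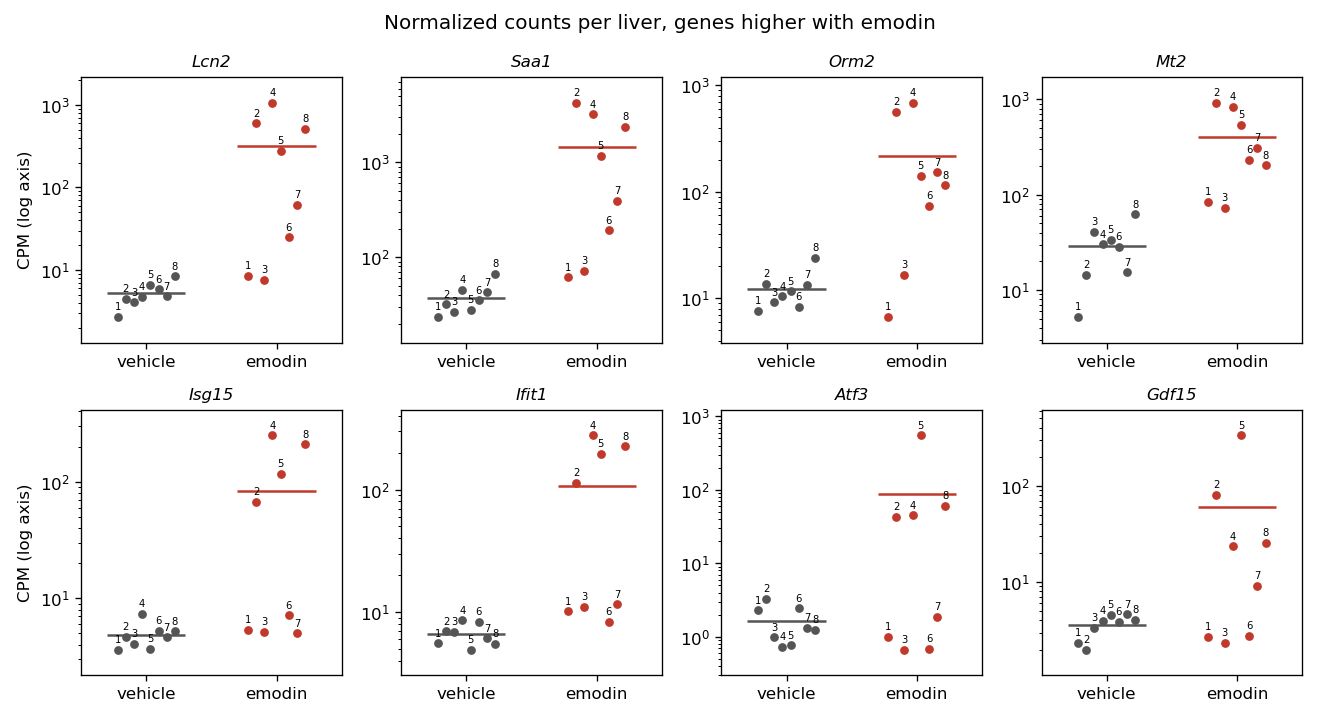
Levels of 8 transcripts that rose with emodin, in CPM on a log axis, with 1 number per liver (its replicate number) and a line at each group mean. Lcn2 lies between 7.66 and 1058 CPM in the emodin livers and between 2.69 and 8.41 CPM in the vehicle livers, and Isg15 is above every vehicle liver in 4 of 8.

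Acute phase and complement genes rose as a group: 25 of the 30 tested members rose, 0 fell and 5 did not pass, and adjusted over the list alone 28 rose. The median log2 fold change of the list was 1.29 (camera adjusted p = 2.74e-25), and its mean was 1.80. The call was lost with a correlation estimated from the data (camera adjusted p = 0.476 with an estimated correlation, the highest over its alternatives, which began at 7.3e-38). The serum amyloid A genes Saa1 and Saa2, neighbours on chromosome 7 whose reads may be shared, rose 39.1-fold and 59.0-fold, Orm2, which encodes an acid glycoprotein of plasma, rose 17.8-fold, and the metallothionein gene Mt1 rose 6.84-fold. These means hide wide differences: Saa2 was at 31.4 and 20.8 CPM in emodin 1 and 3, within the vehicle range (8.89 to 46.6 CPM). Orm2 was at 6.66 and 16.6 CPM there, against 7.68 to 24.1 CPM in the vehicle livers. In the other emodin livers Saa2 ran from 72.4 to 3515 CPM and Orm2 from 73.6 to 685 CPM. Saa1 lay below the highest vehicle liver (66.7 CPM) only in emodin 1 (61.4 CPM). Saa1 and Saa2 were highest in emodin 2, 4, 5 and 8 (1166 to 4254 CPM and 457 to 3515 CPM), the livers that also stood apart for interferon genes. Orm2 followed this only in part, with 152 CPM in emodin 7 against 141 and 115 CPM in emodin 5 and 8. The score of the list was 7.45 ± 0.189 in vehicle livers and 8.92 ± 0.84 in emodin livers, and 7 of 8 emodin livers lay above every vehicle liver (exact two-sided permutation test, adjusted p = 0.0131). Emodin 1 scored 7.71 against a vehicle maximum of 7.78. It was the 1 list of 41 called by fry as well (adjusted p = 0.0131). Array weights ended the calls of Lcn2 (limma adjusted p = 0.0947), Saa2 (0.0535) and Orm2 (0.0884, also lost in the rank-sum test), the highest values of ranges that began at 2.17e-11, 7.8e-10 and 1.33e-07. The log2 fold changes of these 3 genes were then 3.03, 2.95 and 2.28 in place of 5.93, 5.88 and 4.15, and that of Saa1 was 3.0 in place of 5.29. The lowest weights were those of emodin 8, 4 and 5 (0.28, 0.38 and 0.45), with Lcn2 at 507, 1058 and 279 CPM.

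Interferon response genes rose in 16 of 27 tested members, 0 fell and 11 did not pass, with 20 rising when adjusted over the list alone. The median log2 fold change was 1.21 (camera adjusted p = 9.81e-10, adjusted p = 0.594 with an estimated correlation, over alternatives from 2.6e-14, and 0.115 by fry). Isg15, a ubiquitin-like protein, rose 17.3-fold, Rsad2, the antiviral enzyme viperin, 16.6-fold, Ifit1 16.2-fold and Ifit3 12.4-fold. The score of the list in emodin livers 1 to 8 was 4.17, 5.54, 3.73, 6.70, 6.23, 3.87, 3.76 and 6.67, against 3.57 to 4.44 in the vehicle livers, so 4 of 8 lay above every vehicle liver (exact two-sided permutation test, adjusted p = 0.112). Isg15 and Rsad2 lost their call in 7 of 17 alternatives, Ifit3 in 5 and Ifit1 in 2, where array weights gave the lowest log2 fold changes (1.47, 1.44, 1.44 and 1.77). Their edgeR, limma, DESeq2 or rank-sum adjusted p ran from 3.62e-06, 2.87e-06, 6.6e-06 and 4.83e-07 to 0.264, 0.277, 0.157 and 0.141.

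In the heat shock and immediate early list 9 of 21 members rose and 0 fell, 10 when adjusted over the list alone. The median was 0.73 (camera adjusted p = 0.000302, adjusted p = 0.594 with an estimated correlation, over alternatives from 3.88e-06). The transcription factor genes Atf3, Jun and Myc rose by 5.73 ± 1.40, 3.33 ± 0.87 and 3.21 ± 0.66 on the log2 scale (± SE). Of the p53 targets and apoptosis genes 7 of 22 rose and 0 fell, 11 when adjusted over the list alone. The median was 0.44 (camera adjusted p = 0.00068, adjusted p = 0.594 with an estimated correlation, over alternatives from 1.37e-05). They included the stress cytokine gene Gdf15 (log2 fold change 4.06 ± 1.01) and Btg2, an inhibitor of proliferation (2.70 ± 0.67). Emodin 5 carried much of this: without it the values were 3.71 for Atf3, 1.84 for Jun, 2.55 for Gdf15, 1.41 for Btg2 and 0.46 for the median of the immediate early list, and array weights ended the call of this list (camera adjusted p = 0.12). Fos, another member of the immediate early list (2.79, edgeR adjusted p = 0.0319), had 1.72 without emodin 5 and lost its call (edgeR adjusted p = 0.0665). With each of the 16 livers left out in turn, the call of Fos was lost 9 times, and it was lost in 8 of 17 alternatives. Cdkn1a of the p53 list (2.16, edgeR adjusted p = 0.026) lost its call in 7 of 17 alternatives. Atf3, Jun and Gdf15 lost their call in 7 of 17 alternatives and Myc and Btg2 in 2, with values down to 1.12, 0.80, 1.00, 1.63 and 1.29. Adjusted p in edgeR, limma, DESeq2 or the rank-sum test ran from 3.62e-06 to 0.655 for Atf3, 0.000356 to 0.41 for Jun, 5.99e-05 to 0.477 for Gdf15, 4.92e-06 to 0.101 for Myc and 1.17e-05 to 0.0716 for Btg2.

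In the list of ER stress and the integrated stress response 4 of 25 genes rose and 0 fell, and 4 when adjusted over the list alone. The median was 0.25 (camera adjusted p = 0.0407, adjusted p = 0.732 with an estimated correlation). They were Atf3, shared with the immediate early list, Xbp1, Sesn2 and Psat1, an enzyme of serine synthesis, which had a log2 fold change of 2.18 ± 0.59 (1.42 without emodin 8). Xbp1 and Sesn2 had 0.38 ± 0.12 and 0.50 ± 0.16 (edgeR adjusted p = 0.0451 and 0.046). Xbp1 did not pass without vehicle 2, 3, 4, 5, 7 or 8 (0.34, 0.38, 0.37, 0.36, 0.36 and 0.38) or emodin 2, 4 or 5 (0.30, 0.32 and 0.36), and Sesn2 did not without vehicle 1 to 7 (0.47, 0.48, 0.48, 0.47, 0.47, 0.53 and 0.53) or emodin 2, 4 or 5 (0.41, 0.51 and 0.38). Each lost its call in 10 of 17 alternatives (edgeR, limma, DESeq2 or rank-sum adjusted p from 0.0215 to 0.125 and from 0.026 to 0.114). Psat1 lost its call in 7 of 16 alternatives (down to 0.77, with edgeR, limma, DESeq2 or rank-sum adjusted p from 0.000953 to 0.282). The call of the list was lost without vehicle 1, 2 or 4 (medians 0.23, 0.21 and 0.22) and without emodin 2, 4, 5 or 8 (0.23, 0.17, 0.25 and 0.13). Array weights turned its median to -0.028, with adjusted p from 0.0088 to 0.98 over its alternatives. Among glucocorticoid targets 5 of 15 rose and 1 fell, with 6 and 1 when adjusted over the list alone. The median was 0.18 (camera adjusted p = 0.0132, adjusted p = 0.594 with an estimated correlation, over alternatives from 0.000949), while the mean was 1.02. The score of the list was 5.87 ± 0.497 in vehicle and 6.81 ± 0.382 in emodin livers, and 8 of 8 emodin livers lay above the vehicle mean and 5 of 8 above every vehicle liver (exact two-sided permutation test, adjusted p = 0.0163). Those that rose were Lcn2, Mt2 and Mt1, which acute phase signals also induce, Cebpd (0.70 ± 0.19, edgeR adjusted p = 0.0245) and Fkbp5 (0.85 ± 0.27, 0.0479), while Tsc22d3, which encodes a glucocorticoid-induced leucine zipper protein, fell by 0.73 ± 0.15 (edgeR adjusted p = 0.0062). The call of Cebpd was lost in the rank-sum test (adjusted p = 0.0695, against edgeR, limma and DESeq2 values from 0.00602). Fkbp5 kept its call only without vehicle 1, 6 or 8 (0.72, 1.00 and 0.99), had 0.75 to 0.90 without each other liver, and lost it in 5 of 17 alternatives (edgeR, limma, DESeq2 or rank-sum adjusted p from 0.0102 to 0.0861). The median of the glucocorticoid list was 0.29, 0.28, 0.40 and 0.42 without vehicle 3, 5, 6 and 7, and 0.11 without emodin 5, where the call was lost (camera adjusted p = 0.0644).

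NF-κB components and targets rose in 7 of 29 tested members, 0 fell and 22 did not pass, with 15 rising when adjusted over the list alone. The median log2 fold change was 0.46 (camera adjusted p = 0.00015, adjusted p = 0.594 with an estimated correlation, over alternatives from 1.79e-06, and 0.115 by fry). The score was above every vehicle liver in 4 of 8, emodin 2, 4, 5 and 8 (3.79, 3.86, 4.33 and 3.58), the livers that also stood apart for interferon genes, while the other 4 (2.89 to 3.06) lay within the vehicle range (exact two-sided permutation test, adjusted p = 0.112). Cxcl1, a chemokine that attracts neutrophils, rose 3.78-fold and was above every vehicle liver in 7 of 8, Bcl3, a nuclear member of the IκB family, rose 2.34-fold from 8.51 ± 1.49 to 19.9 ± 8.58 CPM and was above every vehicle liver in 8 of 8, and Cxcl10 rose 15.9-fold from 4.25 ± 1.48 to 67.7 ± 89.9 CPM. Cxcl10 lost its call in 7 of 17 alternatives (log2 fold change down to 0.80, with edgeR, limma, DESeq2 or rank-sum adjusted p from 7.57e-05 to 0.754). The subunit genes chosen beforehand did not pass: Nfkb1 had a log2 fold change of -0.01 ± 0.11 (edgeR adjusted p = 0.972) and Rela of 0.40 ± 0.15 (0.0748). Results of the other subunit genes on the list (Nfkb2, Rel and Relb) are not given here. The inhibitor gene Nfkbia had -0.13 ± 0.14 (0.542). Rela passed without emodin 3 (0.46) and without emodin 7 (0.46) but had 0.25 without emodin 5 and 0.22 with array weights, and the sign of Nfkb1 turned with total counts as the scaling (0.037) and without vehicle 4 (0.030), emodin 3 (0.055), emodin 6 (0.051) or emodin 7 (0.028). Ccl2 had 2.22 ± 0.89 (edgeR adjusted p = 0.107), which passed without emodin 7 (2.42) and turned to -0.30 with array weights, and the receptor gene Tlr4 had -0.21 ± 0.21 (0.528). Tnf and Il6 had too few counts for the edgeR test, with 24 and 17 counts over the vehicle livers and 73 and 42 over the emodin livers, or 0.0983 ± 0.107 against 0.228 ± 0.239 CPM for Tnf and 0.0638 ± 0.0702 against 0.155 ± 0.213 CPM for Il6 (exact two-sided permutation p = 0.191 and 0.272). No difference was detected, which does not show that there was none.

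In the NLRP3 inflammasome and pyroptosis list, 0 of 17 genes passed in edgeR and 0 in DESeq2, 0 when adjusted over the list alone, and 1 had an unadjusted p under 0.05. The median log2 fold change was 0.17 (camera adjusted p = 0.243, with 0.135 to 0.732 over its alternatives), which was 0.096 without emodin 5 and 0.091 with array weights. The sensor gene Nlrp3 averaged 0.557 ± 0.217 CPM in vehicle and 0.939 ± 0.449 CPM in emodin livers, a log2 fold change of 0.74 ± 0.30 (edgeR adjusted p = 0.114). The adaptor gene Pycard had 0.28 ± 0.22, the protease gene Casp1 0.17 ± 0.21, the pore-forming Gsdmd 0.30 ± 0.14, and the cytokine genes Il1b and Il18 0.40 ± 0.30 and 0.14 ± 0.11 (edgeR adjusted p from 0.171 to 0.624). Casp1 turned to -0.012 with array weights and to -0.001 without emodin 4.

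**Figure D2:**
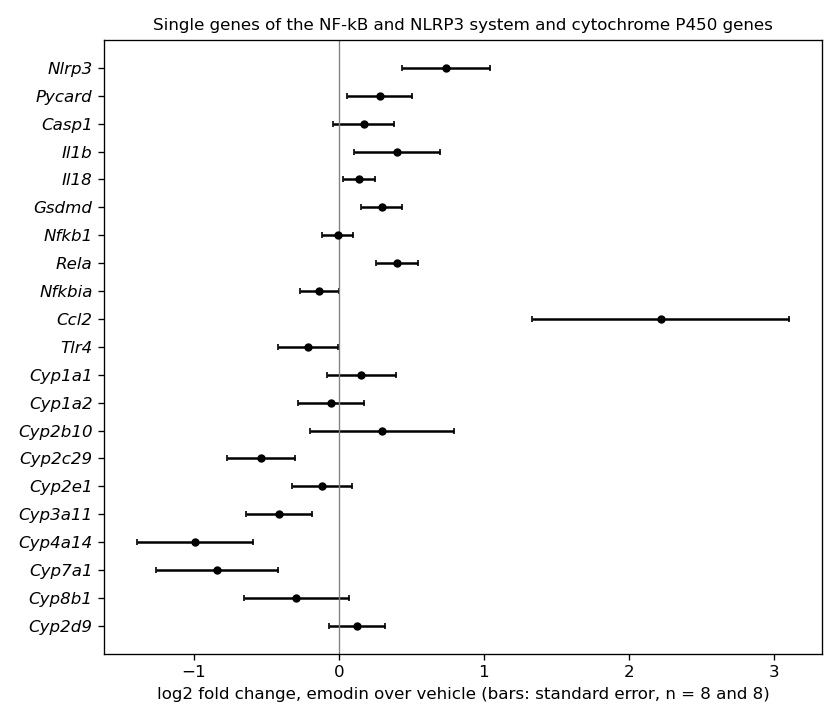
Log2 fold changes (emodin over vehicle, points, with bars of ± 1 SE) of the single genes of the NF-κB and NLRP3 system and of the P450 genes named beforehand. No gene shown passed the edgeR test; Ccl2 is highest at 2.22 and Cyp4a14 lowest at -0.99, and Nfkb1, Cyp2b10 and Cyp2d9 change sign under another scaling (0.037, -0.088 and -0.025).

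Among the 64 tested genes of the P450 family, the main oxidizing enzymes of drug metabolism, 5 fell, 2 rose and 57 did not pass, with 3 falling and 2 rising when adjusted over the list alone. The called share of the family was below the 13.2% called among all tested entries. The median log2 fold change was -0.18 (camera adjusted p = 0.00103, adjusted p = 0.594 with an estimated correlation, over alternatives from 6.12e-05, and 0.13 by fry). The score of the family was lowest in emodin 4 and 8 (5.13 and 4.78), while the other 6 emodin livers (5.591 to 5.93) lay within the vehicle range (5.590 to 6.13). Cyp2a22 fell 2.77-fold from 6.42 ± 2.82 to 2.33 ± 1.17 CPM and Cyp2g1 fell 1.85-fold from 2.57 ± 0.421 to 1.39 ± 0.533 CPM, while Cyp3a13 rose 1.77-fold from 175 ± 23.6 to 309 ± 81.0 CPM. Cyp2u1 fell by 0.82 ± 0.19 on the log2 scale (edgeR adjusted p = 0.0125, with 0.000747 to 0.0533 over its alternatives, where array weights ended the call). The other 3 were weaker calls: Cyp4f14 fell by 0.39 ± 0.12, Cyp2r1 fell by 0.22 ± 0.07 and Cyp4f17 rose by 0.65 ± 0.18 on the log2 scale (edgeR adjusted p = 0.0439, 0.0492 and 0.0286). Cyp4f17 did not pass without vehicle 5 or 7 (0.61 and 0.62) or emodin 2, 4 or 5 (0.57, 0.64 and 0.55). Cyp4f14 kept its call only without vehicle 2 (-0.41) and without emodin 1, 3, 6 or 7 (-0.43, -0.44, -0.41 and -0.42), and Cyp2r1 only without vehicle 6 (-0.26) and without emodin 1 (-0.24), with values in the others from -0.39 to -0.32 and from -0.24 to -0.18. In 17 alternatives these 3 calls were lost 3, 11 and 3 times (Cyp4f14, Cyp2r1 and Cyp4f17), with edgeR, limma, DESeq2 or rank-sum adjusted p from 0.0157 to 0.0625, 0.026 to 0.128 and 0.00874 to 0.093. The P450 genes chosen beforehand did not pass: Cyp1a1 had a log2 fold change of 0.16 ± 0.24, Cyp1a2 -0.05 ± 0.23, Cyp2b10 0.29 ± 0.50, Cyp2c29 -0.54 ± 0.24, Cyp2e1 -0.12 ± 0.21, Cyp3a11 -0.41 ± 0.23, Cyp4a14 -0.99 ± 0.40, Cyp7a1 -0.84 ± 0.42, Cyp8b1 -0.29 ± 0.36 and Cyp2d9 0.12 ± 0.19 (edgeR adjusted p from 0.11 to 0.903). Calls were gained in 1 alternative each by Cyp2c29 (-0.74 with quantile normalization, limma adjusted p = 0.0209, in a range up to 0.18), Cyp7a1 (edgeR adjusted p = 0.0483, in a range up to 0.26) and Cyp4a14 (-1.21 with array weights, limma adjusted p = 0.0412, in a range up to 0.168). Under quantile normalization the signs of Cyp2b10 and Cyp2d9 turned (-0.088 and -0.025), Cyp4a14 passed without emodin 5 (-1.29), Cyp1a2 was 0.012, 0.033 and 0.073 without vehicle 3, emodin 4 and emodin 8, and Cyp2e1 was 0.007 without emodin 8. Por, which encodes the reductase that supplies electrons to microsomal P450 enzymes, rose 1.95-fold from 296 ± 85.8 to 579 ± 144 CPM (edgeR adjusted p = 0.00536).

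Camera called none of the lists of AhR, CAR and PXR, and NRF2 targets, while fry's mixed test, which asks for changes in either direction, called CAR and PXR (adjusted p = 0.00174) and NRF2 (0.00183) and not AhR (0.0535). Of 11 AhR targets 2 rose (Lgals3bp 2.37-fold and Tiparp, which encodes a repressor of this receptor, 1.59-fold), 0 fell and 9 did not pass, with 4 rising when adjusted over the list alone. Array weights ended both calls (limma adjusted p = 0.0614 and 0.092, the highest over alternatives that began at 0.000307 and 0.0024). Lgals3bp was at 89.1 to 169 CPM in emodin 2, 4, 5 and 8, the livers that stood apart for interferon genes. In the other emodin livers it was at 38.9 to 51.2 CPM, against up to 51.0 CPM in the vehicle livers. Tiparp was at 14.9 to 19.3 CPM in the former, at 7.70 to 13.1 CPM in the latter and up to 10.1 CPM in the vehicle livers. The median of this list was -0.05 while its mean was 0.20 and the test pointed up (camera adjusted p = 0.374), and the median was 0.009, 0.024, 0.133, 0.017, 0.033 and 0.073 without vehicle 2, 3 and 8 and emodin 2, 4 and 8. Of 28 CAR and PXR targets 2 rose (Por and Cyp3a13) and 1 fell (Gstt1, 1.40-fold), also when adjusted over the list alone. The median was -0.14 (camera adjusted p = 0.0916). That list passed without vehicle 2 (-0.13), vehicle 4 (-0.17), emodin 6 (-0.13) or emodin 7 (-0.22), and under 5 alternatives, with adjusted p from 0.00525 to 0.732. Its median was -0.087 without vehicle 8. Of 29 NRF2 targets 3 rose and 2 fell, 9 and 3 when adjusted over the list alone. The median was 0.18 (camera adjusted p = 0.172, which reached 0.0466 without a filter in a range up to 0.594), and it was 0.12 without emodin 5 and 0.11 without emodin 8. Cbr3, Srxn1 and Osgin1 rose 3.56-fold, 3.38-fold and 3.09-fold, and Me1 fell 1.72-fold and Gstm4 by 0.33 ± 0.09 on the log2 scale. Srxn1 was at 87.1 to 235 CPM in emodin 2, 4, 5 and 8. In the other emodin livers it was at 27.6 to 41.5 CPM, against up to 30.2 CPM in the vehicle livers. The call of Gstm4 was lost without vehicle 1, 3 or 7 (-0.32, -0.31 and -0.32) or emodin 2 or 4 (-0.29 and -0.30), and in 2 alternatives (edgeR, limma, DESeq2 or rank-sum adjusted p from 0.0096 to 0.0639). Cbr3 and Osgin1 lost their call in 1 alternative each and Srxn1 in 3 (limma or edgeR adjusted p up to 0.0601, 0.0525 and 0.104, from 0.000323, 0.00039 and 0.000618). Over the alternatives the log2 fold change of Cbr3 went from 1.83 down to 0.70, that of Osgin1 from 1.63 to 1.21 and that of Srxn1 from 1.76 to 0.78.

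Camera with its preset correlation called conjugating enzymes and transporters lower, with few single genes that passed, and fry did not call these 3 lists (adjusted p = 0.13, 0.13 and 0.115). Scores of 2 of these lists were lowest in emodin 4 and 8: 5.44 and 5.37 for glucuronosyl- and sulfotransferases (6.02 to 6.43 in the other emodin and 6.13 to 6.61 in the vehicle livers), and 5.27 and 5.18 for transporters (5.54 to 5.81 and 5.65 to 5.896). Of 25 UDP-glucuronosyltransferases and sulfotransferases 1 fell, Sult1c2 (-0.83 ± 0.24, edgeR adjusted p = 0.0298), which did not pass without vehicle 1 (-0.74) or vehicle 5 (-0.81), and 0 passed when adjusted over the list alone. Their median was -0.22 (camera adjusted p = 0.00635, adjusted p = 0.594 with an estimated correlation, over alternatives from 0.00158). Of 23 glutathione S-transferases 4 fell and 0 rose, 4 and 2 when adjusted over the list alone, which were Gstm6 (1.42-fold) and Gstt1 (1.40-fold), each below every vehicle liver in 8 of 8, Gstm7 (-0.38 ± 0.11) and Gstm4 (-0.33 ± 0.09). Gstm7 did not pass without vehicle 2, 3, 5 or 8 (-0.37, -0.37, -0.38 and -0.37) or emodin 2, 4 or 8 (-0.39, -0.33 and -0.33), nor Gstm4 without vehicle 1, 3 or 7 (-0.32, -0.31 and -0.32) or emodin 2 or 4 (-0.29 and -0.30). These 2 calls were also lost in 1 and 2 of 17 alternatives. The median of this list was -0.13 (camera adjusted p = 0.04, adjusted p = 0.619 with an estimated correlation, over alternatives from 0.0161), its mean was -0.008, and the call was lost with array weights (-0.066) and without vehicle 2, vehicle 8, emodin 4, emodin 5 or emodin 8 (-0.11, -0.11, -0.095, -0.099 and -0.072). Of 21 drug and bile acid transporters 1 fell, also when adjusted over the list alone: Abcb11, the bile salt export pump, fell 1.72-fold from 571 ± 80.7 to 332 ± 99.2 CPM (edgeR adjusted p = 0.00687). The median of the transporters was -0.19 (camera adjusted p = 0.0114, adjusted p = 0.594 with an estimated correlation, over alternatives from 0.000555).

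In the fatty acid and triglyceride synthesis list 6 of 19 fell, 0 rose and 13 did not pass, with 9 falling when adjusted over the list alone. Of the emodin livers 7 of 8 scored below every vehicle liver, but the score did not pass (exact two-sided permutation test, adjusted p = 0.0544). The median log2 fold change was -0.47 (camera adjusted p = 2.57e-07, adjusted p = 0.594 with an estimated correlation, over alternatives from 2.98e-10, and 0.0558 by fry). Elovl5, which elongates polyunsaturated fatty acids, fell 2.15-fold from 492 ± 69.2 to 229 ± 60.4 CPM (edgeR adjusted p = 0.000399), Scd1, the stearoyl-CoA desaturase, fell 1.96-fold, Me1, a source of NADPH, 1.72-fold, and Fasn, the fatty acid synthase, 1.65-fold. Of 24 cholesterol synthesis genes 3 fell and 0 rose, also when adjusted over the list alone. The median was -0.12 (camera adjusted p = 0.00145, adjusted p = 0.594 with an estimated correlation, over alternatives from 0.000147). Sc5d (edgeR adjusted p = 4.81e-05) and Stard4, a carrier of cholesterol (1.85-fold, from 143 ± 13.3 to 77.1 ± 16.1 CPM), were below every vehicle liver in 8 of 8. The median of the cholesterol list was -0.047, -0.047, -0.060 and -0.20 without vehicle 4, emodin 6, emodin 7 and emodin 8.

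Of 14 genes of bile acid synthesis and FXR targets 3 fell and 0 rose, 5 when adjusted over the list alone. The median was -0.26 (camera adjusted p = 0.00553, adjusted p = 0.594 with an estimated correlation, over alternatives from 0.00105), which was -0.16 without emodin 8. Hsd3b7, an enzyme early in bile acid synthesis, fell 1.51-fold from 321 ± 28.3 to 213 ± 27.4 CPM (edgeR adjusted p = 0.000806), and Klb, a coreceptor for hormonal fibroblast growth factors, fell 1.69-fold, each in 8 of 8 emodin livers below every vehicle liver. Fgfr4 had -0.24 ± 0.07 (edgeR adjusted p = 0.0309), a call lost in 4 of 17 alternatives (0.0108 to 0.095), without vehicle 1, 4, 5 or 8 (-0.21, -0.23, -0.22 and -0.23) and without emodin 2, 5 or 8 (-0.24, -0.23 and -0.21). Among 32 PPARα targets and genes of fatty acid oxidation 1 rose (Creb3l3, 1.27-fold) and 1 fell (Hadhb, 1.28-fold), also when adjusted over the list alone. The call of Creb3l3 was lost in 1 alternative (edgeR adjusted p = 0.0581, the highest, from 0.00322). The median was -0.13 (camera adjusted p = 0.0882, with 0.0289 to 0.732 over its alternatives). This list passed without vehicle 2 (-0.17), vehicle 4 (-0.16), emodin 2 (-0.10) or emodin 5 (-0.16), and its median came nearest to 0 without emodin 8 (-0.047).

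**Figure D3:**
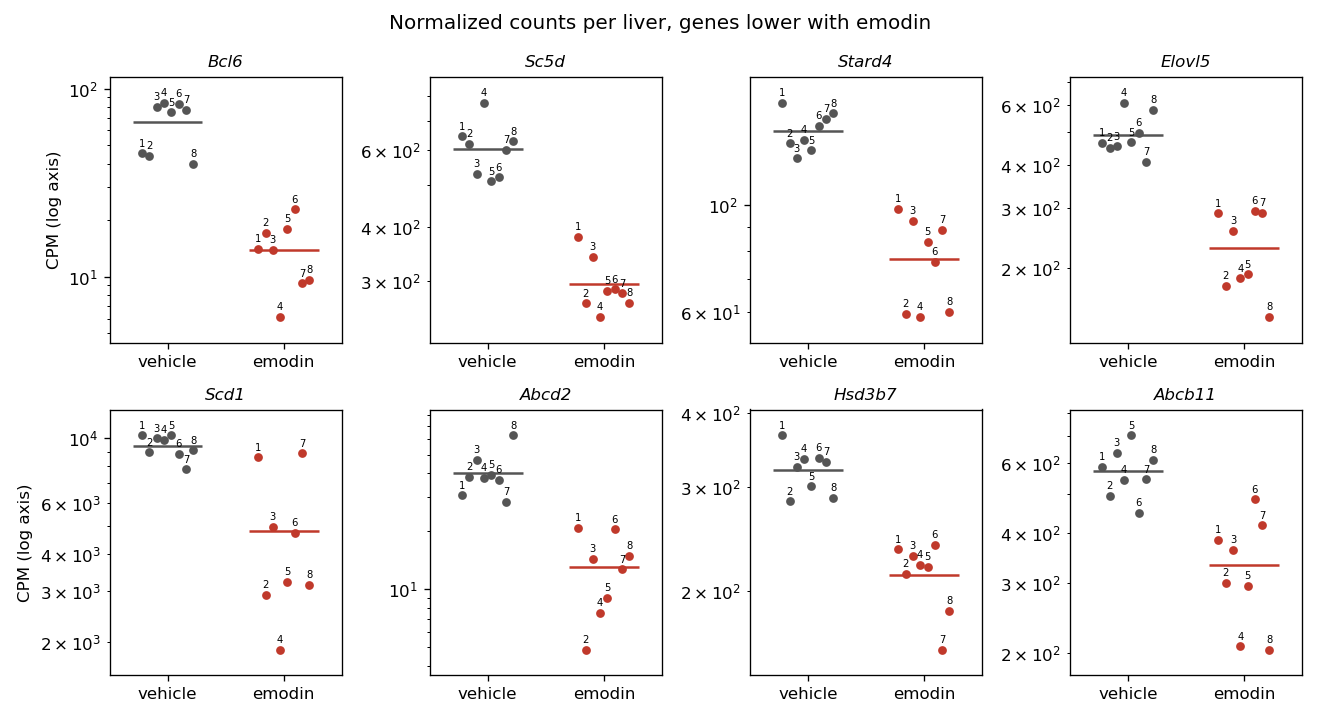
Levels of 8 transcripts that fell with emodin, in CPM on a log axis, with 1 number per liver (its replicate number) and a line at each group mean. Bcl6, Sc5d, Stard4, Elovl5, Abcd2 and Hsd3b7 lie below every vehicle liver in 8 of 8 emodin livers, Abcb11 in 7 and Scd1 in 6.

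Other metabolic groups held single changed genes. In the gluconeogenesis and glycolysis list 1 of 22 rose, the lactate dehydrogenase gene Ldha (1.44-fold, above every vehicle liver in 8 of 8), and 2 fell, Pfkfb3, a regulator of glycolysis (1.94-fold), and Slc2a2, a glucose transporter (-0.50 ± 0.16), also when adjusted over the list alone. Slc2a2 kept its call only without emodin 1, 3, 6 or 7 (-0.58, -0.55, -0.54 and -0.56), had -0.52 to -0.42 without each other liver, and lost it in 3 alternatives (edgeR, limma, DESeq2 or rank-sum adjusted p from 0.0164 to 0.062). The median was -0.08 (camera adjusted p = 0.447). In the amino acid and urea cycle list 3 of 23 rose and 0 fell, also when adjusted over the list alone. The median was 0.12 (camera adjusted p = 0.324). It turned to -0.039 with quantile normalization, and the list passed without emodin 4 (0.21) but had 0.016 without emodin 7. Nags, which makes the activator of the urea cycle, rose 1.35-fold from 29.0 ± 2.84 to 39.1 ± 2.83 CPM (edgeR adjusted p = 0.00114), and Asl and Arg1, enzymes of that cycle, rose 1.58-fold and 1.30-fold. The call of Asl was lost in the rank-sum test (adjusted p = 0.0695, against edgeR, limma and DESeq2 values from 0.00144) and that of Arg1 with quantile normalization (limma adjusted p = 0.0902, from 0.000136). Of 79 cytosolic ribosomal protein genes 6 rose, 0 fell and 73 did not pass, with 0 passing when adjusted over the list alone, but 76 had a positive log2 fold change. The median was 0.19 (camera adjusted p = 1.42e-07, adjusted p = 0.639 with an estimated correlation, over alternatives from 1.54e-10). With 1 of the 16 livers left out in turn, the calls of Rps27, Rpl37, Rpl12 and Rps26 were lost 6, 7, 13 and 9 times. In 17 alternatives they were lost 2, 2, 10 and 0 times. Of 79 nuclear genes of the mitochondrial respiratory chain 0 passed in edgeR and 2 in DESeq2, both lower, 0 when adjusted over the list alone, and 8 had an unadjusted p under 0.05. The median was -0.02 (camera adjusted p = 0.154). Atp5g3 had -0.29 ± 0.10 (edgeR adjusted p = 0.0512) and passed without vehicle 3 (-0.32) or emodin 7 (-0.33) and in 14 of 17 alternatives (0.0188 to 0.105), and Cox5a had -0.31 ± 0.11 (edgeR adjusted p = 0.0708) and passed without emodin 7 (-0.34) and in 2 alternatives (0.0325 to 0.152). The list itself passed without vehicle 3 (-0.046), emodin 2 (-0.069), emodin 3 (-0.051) or emodin 6 (-0.079), and its median was 0.041, 0.018 and 0.044 without vehicle 2, emodin 5 and emodin 8. Of 13 mitochondrially encoded mRNAs 0 passed in edgeR, 0 in DESeq2, 0 at an unadjusted p under 0.05 and 0 over the list alone. The gene mt-Nd4l had -0.33 ± 0.16, which passed with quantile normalization (-0.45, limma adjusted p = 0.0314, in a range up to 0.245), and the median of the list was -0.16 (camera adjusted p = 0.058). That list passed in 10 alternatives (adjusted p from 0.00491 to 0.732 over all of them) and without vehicle 2, 4 or 6 (-0.17, -0.18 and -0.17) or emodin 2, 3, 6 or 7 (-0.19, -0.17, -0.18 and -0.21).

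Of 28 cell cycle genes 0 passed in edgeR, 3 were higher in DESeq2, 0 passed over the list alone and 5 were higher at an unadjusted p under 0.05. The median was 0.13 (camera adjusted p = 0.154). The replication helicase gene Mcm5 had 1.29 ± 0.42 (edgeR adjusted p = 0.0525), which passed without emodin 3 (1.42) or emodin 7 (1.45) and in 2 of 16 alternatives (0.0147 to 0.28). It had 0.80 without emodin 8 and 0.54 with array weights. The list passed without emodin 2 (0.21) or emodin 5 (0.23), and its median was 0.029 without emodin 8. Of 17 clock genes 2 rose and 1 fell, 3 and 1 when adjusted over the list alone. The median was 0.27 (camera adjusted p = 0.286). Per2 and Cry2 rose 1.39-fold and 1.23-fold, and the repressor gene Nr1d1 fell 1.98-fold, a call lost in the rank-sum test (adjusted p = 0.0695, against edgeR, limma and DESeq2 values from 0.000412). Among 21 male-biased liver genes 2 rose and 3 fell, also when adjusted over the list alone, with a median of -0.02, a mean of 0.03 and a test that pointed down (camera adjusted p = 0.898); Elovl3, an elongase, fell 2.48-fold, and the complement genes C6 and C8a rose 1.58-fold and by 0.46 ± 0.10 on the log2 scale. The third gene to fall beside Elovl3 and Cyp2u1 was Nudt7 (-0.69 ± 0.22, edgeR adjusted p = 0.0461). Nudt7 passed only without vehicle 2, 5 or 8 (-0.73, -0.75 and -0.76) or emodin 1, 3, 5 or 6 (-0.74, -0.75, -0.75 and -0.76), had -0.74 to -0.58 without each other liver and lost its call in 4 of 17 alternatives (adjusted p from 0.0126 to 0.128 in edgeR, limma, DESeq2 or the rank-sum test). C6 lost its call in 2 alternatives (edgeR or rank-sum adjusted p up to 0.0695, from 0.00422). The sign of that median turned without any of vehicle 1, 2, 3, 4, 6 or 7 and emodin 1, 2, 4, 5, 7 or 8, where it lay between 0.014 and 0.126. Among 14 female-biased genes 1 fell, Abcd2, also when adjusted over the list alone. The median was -0.21 (camera adjusted p = 0.0751), and the list passed without vehicle 1, 4 or 7 (-0.29, -0.20 and -0.26) or emodin 2 or 7 (-0.17 and -0.18) but had -0.061 without vehicle 8. Of 20 genes of fibrosis and matrix 1 fell and 0 rose, 0 when adjusted over the list alone. It was the collagen gene Col5a1 (-0.40 ± 0.13, edgeR adjusted p = 0.0462). Col5a1 passed only without vehicle 1 or 7 (-0.43 and -0.43) or emodin 7 or 8 (-0.43 and -0.44), had -0.41 to -0.33 without each other liver and lost its call in 6 of 16 alternatives (adjusted p from 0.0188 to 0.116 in edgeR, limma, DESeq2 or the rank-sum test). The median was -0.22 (camera adjusted p = 0.173), which was -0.034 without vehicle 2.

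Markers of the liver's zones and other cells showed few calls. Of 16 pericentral markers 2 fell and 0 rose, also when adjusted over the list alone, with Nkd1 down 1.35-fold. The other was Lgr5 (-0.71 ± 0.23, edgeR adjusted p = 0.0454). Lgr5 passed only without vehicle 6 or 8 (-0.75 and -0.77) or emodin 1, 3 or 6 (-0.85, -0.75 and -0.80), had -0.75 to -0.60 without each other liver and lost its call in 5 of 16 alternatives (adjusted p from 0.0155 to 0.0969 in edgeR, limma, DESeq2 or the rank-sum test). The median was -0.04 (camera adjusted p = 0.233), which was 0.051 without emodin 8. Of 16 periportal markers 3 rose (Asl, Arg1 and Sdsl) and 1 fell (Alb), also when adjusted over the list alone. The call of Sdsl was lost in the rank-sum test (adjusted p = 0.0695, against edgeR, limma and DESeq2 values from 0.00665). The median was -0.11 (camera adjusted p = 0.662). Markers of T and NK cells fell in 2 of 14, 3 when adjusted over the list alone. The median was -0.83 (camera adjusted p = 0.00268, adjusted p = 0.594 with an estimated correlation, over alternatives from 0.00059), which was -0.45 without vehicle 7; the T cell kinase gene Lck fell 1.99-fold from 1.78 ± 0.549 to 0.89 ± 0.391 CPM. The other call, Cd2 (-0.90 ± 0.29, edgeR adjusted p = 0.0498), held only without emodin 2 (-1.02) or emodin 6 (-0.99), with -0.96 to -0.72 without each other liver, and was lost in 6 of 15 alternatives (0.0272 to 0.0901). B and plasma cell markers fell in 1 of 9, also when adjusted over the list alone. The median was -0.57 (camera adjusted p = 0.00492, adjusted p = 0.594 with an estimated correlation, over alternatives from 0.000451). Markers of sinusoidal endothelium fell in 3 of 15, 5 when adjusted over the list alone. The median was -0.30 (camera adjusted p = 0.0118, adjusted p = 0.594 with an estimated correlation, over alternatives from 0.00378), and this call was lost without vehicle 5 (-0.22). Ehd3, which serves membrane traffic, fell 1.62-fold and Kdr, a receptor for vascular endothelial growth factor, 1.37-fold. Tek (-0.49 ± 0.14, edgeR adjusted p = 0.0265) did not pass without vehicle 1 or 5 (-0.46 and -0.42) or emodin 4 (-0.46), nor in 3 of 17 alternatives (0.00787 to 0.0695). Stellate cell markers fell in 1 of 14, also when adjusted over the list alone. It was Rgs5 (-0.72 ± 0.21, edgeR adjusted p = 0.0332; -0.48 without vehicle 2), which did not pass without vehicle 3 or 7 (-0.69 and -0.71) or emodin 2, 4, 5 or 6 (-0.67, -0.70, -0.70 and -0.69), nor in 4 of 17 alternatives (0.00671 to 0.0881). The median was -0.25 (camera adjusted p = 0.0321, adjusted p = 0.594 with an estimated correlation, over alternatives from 0.01), and this call was lost with array weights (-0.13) and without vehicle 2, 6 or 8 (-0.26, -0.22 and -0.22) or emodin 2 or 5 (-0.22 and -0.21).

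No marker of Kupffer cells and macrophages (18), neutrophils (4), cholangiocytes (10) or erythroid cells (7) passed in edgeR, over all entries or over the list alone, while DESeq2 called 1 of the macrophage and 1 of the cholangiocyte markers higher, and 1 and 1 were higher at an unadjusted p under 0.05. Their medians were 0.32, 0.23, 0.04 and -0.32 (camera adjusted p = 0.165, 0.713, 0.969 and 0.215). The macrophage list passed without vehicle 4 (0.50), where its gene Cd68 passed too (1.06 against 0.85 ± 0.33), and without a filter (adjusted p = 0.0426, in a range up to 0.751), while it had 0.17 without emodin 5. S100a8, a neutrophil protein, had 0.90 ± 0.50, the cholangiocyte transcription factor gene Sox9 1.15 ± 0.46 and the globin gene Hbb-bt -0.47 ± 0.26 (edgeR adjusted p from 0.105 to 0.241). Sox9 passed in DESeq2 (adjusted p = 0.0358) and had 0.024 with array weights (limma adjusted p = 0.973, the highest of its range). Without emodin 8 it had 0.74, S100a8 had 0.53 without emodin 4, and Hbb-bt had -0.20 without vehicle 2. The sign of the cholangiocyte median turned without vehicle 7 (-0.030) or emodin 4 (-0.11). Skeletal muscle transcripts were present in 2 livers, vehicle 2 and emodin 7: Acta1, the actin of skeletal muscle, reached 1000.2 and 243 CPM there and at most 0.0669 CPM in each of the other 14. Of the 3 tested markers of gut epithelium and muscle 1 fell, also when adjusted over the list alone. It was Fabp2 (-0.30 ± 0.10, edgeR adjusted p = 0.0491). Fabp2 passed only without vehicle 8 (-0.33) or emodin 1 or 3 (-0.35 and -0.34), had -0.32 to -0.25 without each other liver and lost its call in 7 of 17 alternatives (adjusted p from 0.0263 to 0.132 in edgeR, limma, DESeq2 or the rank-sum test). The median was -0.31 (camera adjusted p = 0.183). Adipose markers rose in 1 of 5, also when adjusted over the list alone. The median was -0.45 (camera adjusted p = 0.898), which was 0.12 without vehicle 2, the liver with most muscle transcripts; Cidec, a lipid droplet protein also made in fatty livers, rose 3.49-fold from 2.30 ± 0.587 to 8.06 ± 5.63 CPM. Of the exocrine pancreas list 2 genes were measured, too few for a list test, and 0 passed in edgeR or DESeq2, 1 lower over the list alone and at an unadjusted p under 0.05. The median was -0.32. Leaving out both livers with muscle transcripts, an alternative chosen after seeing the data, gave 1187 higher and 836 lower calls.

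**Figure D4:**
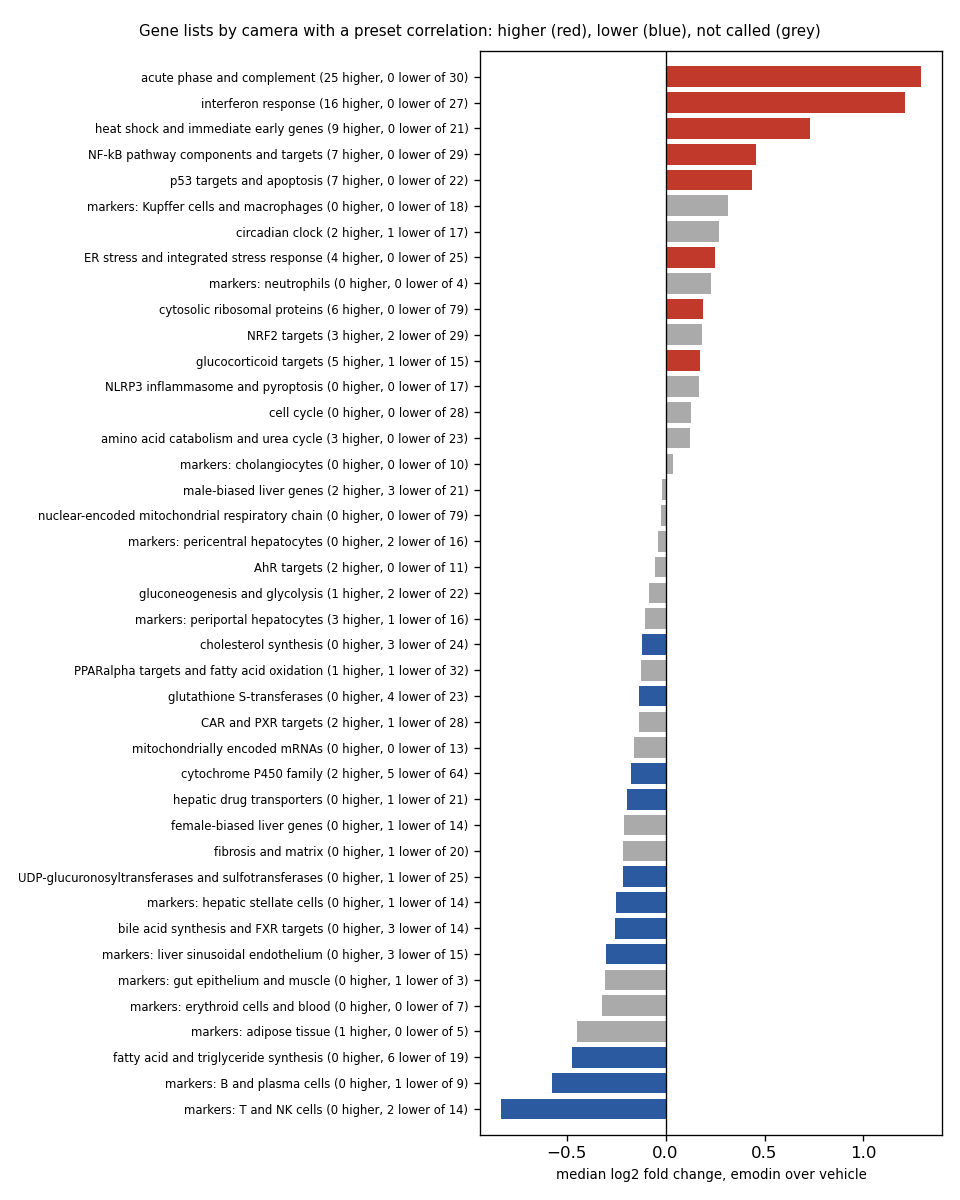
Median log2 fold change (emodin over vehicle) of the tested members of each of 41 gene lists, as bars from 0, red or blue where camera with its preset correlation called the list higher or lower and grey where it did not. The acute phase list is highest at 1.29 and the T and NK cell markers lowest at -0.83; none of the 19 calls held with an estimated correlation, and the amino acid list turns to -0.039 with quantile normalization.

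The emodin livers differed more among themselves than the vehicle livers did. The median SD of log2 CPM within a group was 0.214 for vehicle and 0.308 for emodin, and the SD was larger in the emodin group for 70.2% of the tested entries. Correlations of log2 CPM across genes between livers had a median of 0.975 within vehicle, 0.962 within emodin and 0.961 between the groups (genes are not independent replicates), and no 2 libraries were duplicates. The first principal component held 29.1% of the variance, with vehicle livers between -30.9 and -13.2 and emodin livers 1 to 8 at -8.2, 34.4, -10.0, 63.4, 53.2, -4.6, -9.5 and 62.0. Of the control genes, Actb had a log2 fold change of 0.54 ± 0.25, Gapdh of 0.52 ± 0.27 and Ppia of 0.21 ± 0.14 (edgeR adjusted p from 0.164 to 0.353). Alb fell by 0.50 ± 0.15 on the log2 scale (edgeR adjusted p = 0.0309), a call lost without vehicle 3, 4, 5 or 8 (-0.46, -0.49, -0.49 and -0.48) or emodin 2 or 5 (-0.47 and -0.48). It was also lost in 3 of 17 alternatives (edgeR or limma adjusted p from 0.00238), among them quantile normalization, which sets the most abundant genes of all livers to equal values.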

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

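All tests in this part were chosen only after the result was seen. A liver stood out where its gap to the nearest other liver of its group was too large a part of the group's range by Dixon's test at the 95% level. Of 412 groups examined (160 genes, 42 list scores and 4 measures of the libraries, each in both groups) 21 stood out, and chance gives about 1 in 20 groups, or 20.6 here.

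Emodin 5 had 324 CPM of Btg2 (12.2 to 43.1 CPM in the other emodin livers) and 0.676 CPM of Il6 (0.0447 to 0.138 CPM). Vehicle 1 had the lowest Cdkn1a of its group (1.09 CPM), the highest Osgin1 (96.5 CPM), the lowest Tlr4 (0.725 CPM) and the lowest score of the p53 list (2.91 log2 CPM). Vehicle 4 had the highest Icam1 of its group (10.98 CPM), the lowest clock score (4.53 log2 CPM) and the highest score of B and plasma cell markers (3.36 log2 CPM). Emodin 8 had the lowest Il18 (7.998 CPM) and the lowest score of B and plasma cell markers (0.502 log2 CPM) among the emodin livers. Further single values were Eda2r in vehicle 6 (0.280 CPM, the lowest), Gstt1 in vehicle 8 (243 CPM, the highest), Fasn in emodin 1 (289.6 CPM, the highest) and Setd4 in emodin 3 (3.19 CPM, the lowest). Vehicle 2 had the highest Rgs5 (88.8 CPM), the highest adipose score (6.22 log2 CPM) and the highest score of gut and muscle markers (6.07 log2 CPM) of its group. Emodin 7 had the highest score of gut and muscle markers (5.33 log2 CPM), no counts of Cela2a (0 CPM) and the lowest score of exocrine pancreas markers (-0.667 log2 CPM) of its group.

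Chance alone is an unlikely source of the difference between the groups. The real split of the livers called 1884 entries and 376 of them at least 2-fold, while the highest of the other random splits called 1 and 1. Of the 100 splits, 1 (the real one) gave as many, for either count, and with 100 splits this share cannot be smaller. The other splits had 4 to 6 emodin livers on 1 side, so the difference between the real groups widened the spread within theirs. Splits of this kind cannot tell emodin from a batch or from handling that differed between the groups.

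Skeletal muscle transcripts stood far above the other livers in vehicle 2 and emodin 7, with 5670 and 1586 CPM summed over 20 muscle genes against at most 35.5 CPM in the other 14. All 20 listed genes were higher in these 2 livers than in each other liver, with ratios of vehicle 2 to emodin 7 from 1.39 to 5.69 (median 3.82), which is consistent with skeletal muscle carried over at dissection, although 11 of the 20 had been seen before the list was written. An effect of emodin is argued against, since 1 emodin liver and 1 vehicle liver passed 10 CPM of Acta1. Libraries of another tissue are argued against by the Alb share, which was at least 1.03 times the lowest share of the other livers of the same group. The labels hold no record of dissection, so the source stays a hypothesis.

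Interferon, immediate early and stress transcripts differed widely between emodin livers: in livers 1 to 8 Atf3 was 1.00, 42.5, 0.671, 45.0, 552, 0.693, 1.89 and 60.3 CPM, and Isg15 was 5.35, 67.5, 5.14, 250, 117, 7.15, 5.01 and 208 CPM. The scaling of the libraries is argued against: livers 2, 4, 5 and 8 stayed above the other 4 in the interferon and immediate early scores under 4 other scalings. The smallest gap was 0.72 log2 CPM (immediate early) and 1.32 (interferon), against 0.73 and 1.37 with TMM. More leukocytes in the tissue cannot be told apart from a response of the liver cells, because marker scores went with the pattern in some livers and not in others. Macrophage and neutrophil scores were above those of the other 4 emodin livers in 2 of these 4 livers (emodin 4 and 5), and T and NK cell and B and plasma cell scores in 1 each. The macrophage score was 4.28 and 4.33 in emodin 4 and 5, at most 3.48 in the other 6 emodin livers and up to 4.53 in the vehicle livers. A delay or handling at collection cannot be told apart either, since the series gives no record of collection order or times to set against the immediate early score, high in 4 of 8. Library measures moved with the pattern in part: mitochondrial transcripts took 8.98, 8.23 and 8.41% of the counts in emodin 4, 5 and 8, 11.7% in emodin 2 and 10.5 to 12.8% in the remaining 12 livers, and the TMM factors of emodin 4 and 8 (1.13 and 1.16) were the highest. An effect of emodin that differs in strength or timing between mice stays open as well, and it was not tested apart from these.

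Some genes had no counts in several livers and at least 5 CPM in others of the same group: 12 entries, 10 of them annotated and 10 tested, with 0 called by edgeR. Commd1b, for instance, was at 0 in vehicle 1 and in emodin 1, 2, 4 and 8, and at 27.9 CPM in emodin 5. Reads assigned whole to 1 of 2 overlapping genes may account for it: 8 of the 10 annotated entries (80%) overlap another gene on the same strand against 23.6% of the other annotated genes that reached 5 CPM in a liver (10158 genes in all, odds ratio 12.92, Fisher's exact two-sided p = 0.000277). No biological explanation was tested.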

How the results depend on the processing

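The tests with DESeq2, a filter at 5 CPM, totals as the only scaling, limma on log2 CPM, annotated genes alone, halved counts and 2 livers left out were chosen only after the result was seen; the others were planned. The pseudocounts, the filter at a mean of 5 and the rescaling to a common total had been planned on FPKM and were run on CPM, since the table holds counts. Of the values of named genes outside the left-out livers, 2366 kept their direction and their side of the threshold, 234 lost a call, 27 gained one and 13 changed sign, and of the list medians 605, 46, 25 and 18 did. With single livers left out these numbers were 2253, 252, 12 and 11 for genes and 584, 19, 28 and 25 for lists. DESeq2 called 2532 entries, 1883 of them shared with the 1884 of edgeR. For the changes below the cause was not tested, except where fewer entries or livers entered the test.

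With a correlation estimated from the data, 0 of 19 list calls remained, and with fry 1 (acute phase). The list medians were then as before: P450 family -0.18, NF-κB 0.46, glucuronosyl- and sulfotransferases -0.22, glutathione S-transferases -0.13, transporters -0.19, bile acids -0.26, cholesterol -0.12, fatty acids -0.47, ribosomal proteins 0.19, acute phase 1.29, interferon 1.21, ER stress 0.25, p53 0.44, immediate early 0.73, glucocorticoid 0.18, T and NK cells -0.83, B and plasma cells -0.57, endothelium -0.30 and stellate cells -0.25. This follows from the test, since an estimated correlation widens the null spread of lists whose members vary together.

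Without a filter the medians were 0.11 for AhR (sign turned), 0.059 for male-biased genes (turned) and -0.022 for cholangiocytes (turned), and CAR and PXR (-0.15), NRF2 (0.20), PPARα (-0.14), mitochondrial mRNAs (-0.16), female-biased genes (-0.21) and macrophages (0.36) passed. With a mean of at least 5 CPM, which leaves fewer entries, 158 entries were at least 2-fold higher and 34 lower, ER stress no longer passed (0.18), CAR and PXR (-0.22), PPARα (-0.15), mitochondrial mRNAs (-0.17) and female-biased genes (-0.17) passed, and AhR (0.15) and male-biased genes (0.043) turned. With totals as the only scaling CAR and PXR (-0.11), mitochondrial mRNAs (-0.14) and female-biased genes (-0.18) passed and Nfkb1 turned (0.037). Without the 50 most abundant genes in the scaling mitochondrial mRNAs passed (-0.19). With annotated genes alone, 76 were at least 2-fold lower and mitochondrial mRNAs passed (-0.17). The rank-sum test gave 135 entries at least 2-fold higher and 104 lower.

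Limma on log2 CPM with pseudocounts of 1, 0.1 and 0.01 gave 80, 148 and 150 entries at least 2-fold higher and 48, 130 and 138 lower. In these fits Cyp2b10 turned (-0.057, -0.12 and -0.13), mitochondrial mRNAs passed (-0.19 in each) and ER stress did not (0.22 in each). Quantile normalization gave 76 higher and 50 lower at 2-fold, turned Cyp2b10 (-0.088), Cyp2d9 (-0.025) and the amino acid list (-0.039), and let CAR and PXR (-0.17) and mitochondrial mRNAs (-0.21) pass. Array weights, between 0.28 and 1.94 per liver, were lowest in emodin 8, 4 and 5 (0.28, 0.38 and 0.45). These livers stood apart for interferon genes, as did emodin 2 (0.79), so this setting gives the livers with the strongest rises less say. Vehicle 2 had 0.71, and the other emodin livers had 1.02 to 1.44. The weights gave 94 entries at least 2-fold higher and 102 lower. They turned Casp1 (-0.012), Ccl2 (-0.30), Cyp1a2 (0.053), Cyp2b10 (-0.054), AhR (0.053), gluconeogenesis (0.047), respiratory chain (0.088), ER stress (-0.028), male-biased genes (0.25), pericentral (0.002), periportal (0.002) and cholangiocyte markers (-0.17). Glutathione S-transferases (-0.066), immediate early genes (0.47) and stellate markers (-0.13) no longer passed with them, and the amino acid list did (0.14).

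The replicate numbers do not pair the livers: 1 of 8 pairs of equal number had a correlation of deviations over 0.1 (-0.15 to 0.25), and 2 of 8 vehicle livers correlated best with their own number. As a block they gave 628 entries higher, 635 lower, 108 at least 2-fold higher, 112 at least 2-fold lower, a turned Cyp2b10 (-0.002) and an ER stress list that did not pass (0.22), with fewer degrees of freedom and no pairing to remove.

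Without both livers that held muscle transcripts, Nfkb1 (0.014), Cyp2b10 (-0.071), AhR (0.016), respiratory chain (0.017), male-biased genes (0.080) and adipose markers (0.083) turned, CAR and PXR (-0.20), PPARα (-0.20), mitochondrial mRNAs (-0.23) and female-biased genes (-0.26) passed, and glucocorticoid targets did not (0.16).

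With each liver left out in turn, higher calls ranged from 709 to 1333, lower calls from 521 to 903, and 2-fold higher calls from 167 to 324. Log2 fold changes ranged from -0.34 to 0.12 for Cela2a, -0.001 to 0.24 for Casp1, -0.066 to 0.055 for Nfkb1, -0.20 to 0.073 for Cyp1a2 and -0.17 to 0.007 for Cyp2e1. Other ranges were 0.25 to 0.46 for Rela, 0.80 to 1.45 for Mcm5, 0.53 to 1.21 for S100a8, 0.74 to 1.32 for Sox9, -0.59 to -0.20 for Hbb-bt, 0.17 to 0.38 for Pycard, -0.25 to -0.076 for Nfkbia, -0.32 to -0.13 for Tlr4, 0.048 to 0.31 for Cyp1a1, 0.004 to 0.52 for Cyp2b10, -0.45 to -0.16 for Cyp8b1, 0.023 to 0.22 for Cyp2d9 and 0.23 to 0.63 for Gapdh. List medians ranged from -0.14 to -0.018 for gluconeogenesis, -0.14 to -0.028 for periportal, -0.33 to -0.034 for fibrosis, 0.068 to 0.38 for neutrophil and -0.41 to -0.13 for erythroid markers, 0.096 to 0.24 for NLRP3 and 0.11 to 0.25 for NRF2. They ranged from -0.078 to 0.13 for AhR, -0.22 to -0.087 for CAR and PXR, -0.17 to -0.072 for glutathione S-transferases, -0.17 to -0.047 for PPARα, 0.016 to 0.21 for amino acids, -0.079 to 0.044 for the respiratory chain, -0.21 to -0.11 for mitochondrial mRNAs, 0.13 to 0.32 for ER stress and 0.029 to 0.24 for cell cycle. They ranged from 0.11 to 0.42 for glucocorticoid targets, -0.084 to 0.13 for male-biased and -0.29 to -0.061 for female-biased genes, -0.11 to 0.051 for pericentral, 0.17 to 0.50 for macrophage, -0.37 to -0.22 for endothelial, -0.30 to -0.21 for stellate, -0.11 to 0.16 for cholangiocyte and -0.60 to 0.12 for adipose markers.

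The depth limits what can be said of Tnf and Il6, with 24 and 17 counts over all vehicle livers, and on simulated data of this comparison 38.8% of genes changed 1.5-fold were called, so genes that did not pass are not shown to be unchanged.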

Other observations

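All tests in this part, and the genes named in it, were chosen only after the result was seen. The changes with the smallest p-values lay outside the lists apart from Sc5d. Setd4, a member of the SET-domain methyltransferases, fell 2.38-fold from 10.4 ± 1.70 to 4.38 ± 0.571 CPM, Camk1d, a calcium-dependent kinase, fell 2.32-fold from 91.1 ± 12.0 to 39.3 ± 7.35 CPM, and Atxn1 fell 2.12-fold (mean ± SD, n = 8 per group, edgeR adjusted p from 2.1e-05 to 3.18e-05). Scara5, a receptor for ferritin, rose 14.3-fold from 2.78 ± 1.94 to 39.8 ± 7.86 CPM (edgeR adjusted p = 0.000138), and Fndc3b rose 2.60-fold. Fads3, a relative of the fatty acid desaturases, fell 2.58-fold, and Calcrl, the receptor that binds adrenomedullin, fell 1.84-fold. In these genes all 8 emodin livers lay beyond all 8 vehicle livers, and every alternative and every left-out liver kept the call (highest adjusted p 0.00788 over the alternatives).

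Complete separation of the groups was found for 282 of 14308 tested entries, 134 with every emodin liver above every vehicle liver and 148 with every one below, where chance would give 2.2. Of these, 279 were called by edgeR, and 7 of the 134 were on the acute phase, interferon or immediate early lists. Loci without an Ensembl ID made up 14.8% of the lower calls and 6.7% of the higher ones, against 10.1% of the tested entries (odds ratio 2.42, Fisher's exact two-sided p = 1.55e-08). That test takes entries as independent of each other, so its p does not measure the spread between livers.

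Of genes that growth hormone induces, Socs2 fell (log2 fold change -1.66 ± 0.40, edgeR adjusted p = 0.0147), Cish rose (1.54 ± 0.40, edgeR adjusted p = 0.0197) and Igf1 had -0.12 ± 0.10 (0.47), while Bcl6, which that hormone represses, fell (-2.25 ± 0.26). The call of Socs2 was lost in 2 of 17 alternatives (edgeR or rank-sum adjusted p up to 0.0613, from 0.00012). The call of Cish was lost with array weights (limma adjusted p = 0.108, the highest over its alternatives, which began at 0.000511) and in 2 other alternatives.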
